A study of Mus musculus with 12 samples.

How the data were processed

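Total RNA of mouse liver was extracted with Trizol and RNeasy columns that remove genomic DNA, labelled as biotinylated cRNA and hybridized to Illumina Mouse-6 V2 BeadChips, per the labels' protocols. The 12 arrays fell into 6 with icv leptin and 6 with icv PBS by the labels' sample group. The infusion's dose, volume and day came from the series' design text.

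The deposited signals are intensity values per probe and array, called AVG_Signal per the file headers, with a detection p-value for each. The sorted signals of the 12 arrays differed by a median of 0 percent of their mean, so the deposited intensity values had already been made equal in distribution between arrays, although the table is named as not normalized. The software that did so is not given in the sources used here. The signals had no background subtracted, with a lowest value of 95.9 and a median of 118.9. The authors' log2 values in the series matrix equalled log2 of these signals, without centring. The authors' deposited Cyber-T table, named so per the file headers, gives a p-value and a log2 difference of group means per probe, unadjusted.

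Of the 45281 probes, 34885 had 1 gene symbol in the GEO platform annotation, 18 had several and 10378 had none here. Of the 34885 symbols, 34807 were found by gene identifier in a RefSeq table of assembly GRCm38.p6, and 0 changed. No genome build is given in the sources used here, so no coordinates are printed.

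Signals were corrected and normalized with limma's neqc, which takes the background from the detection p-values, adds an offset of 16, quantile normalizes and takes log2. Because of that offset a fold difference understates the change of dim genes. Probes were kept when the detection p was below 0.01 on at least 3 of 12 arrays, which left 15062, of which 13068 had 1 symbol and 1994 did not. Each gene was represented by its kept probe of highest mean, giving 8819 genes. The groups were compared with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). Of 524 called genes with over 1 kept probe, all kept probes were called the same way in 250, a kept probe was not called in 272, and in 5 a kept probe was called the opposite way. Among called named genes, 1 of 2 kept probes was called for Gys2, Apoc2, Oasl2, Atp5a1 and Serpina1a, 2 of 3 for Tpi1, 3 of 4 for Nudt7, 1 of 3 for Cdkn1a and 1 of 4 for Acta2. A gene detected on no array of a group is given as a bound, against the lowest signal of detected probes on each array or the probe's own value if higher.

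The 36 gene lists, of pathways, cell types and handling, held 667 entries, of which 604 were named on the array. The 30 lists with at least 4 tested members were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists, and with an estimated correlation and fry as alternatives. The named genes were the 12 greatest rises and falls past the threshold, up to 4 members of each list with the greatest absolute difference among those past it (up to 2 where none passed), 20 genes fixed by name and any gene that a rule of the closing section picked out. Of those fixed by name, some were not analysed here. The Fasn probe was detected on 2 arrays, and the Cpt1a and Lepr probes on 0, so these were not tested. Groups, tests, lists and this rule were fixed before the data were examined. Genes named outside it are said to be chosen after their values were seen.

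The fit was tested on simulated data with 200 of 8819 genes changed between leptin and PBS. It recovered 35.3% of genes at a log2 change of 0.5, 77.3% at 1 and 97.0% at 2, and 4.14% of its 145 calls were unchanged genes. The simulated noise was normal and independent between genes, and the real comparison called 16.7% of genes. These rates need not hold for the real data. Alternatives were other background and normalization methods, the deposited log2 values, filters, probe rules, variance models, array weights, a replicate block, the authors' p-values, a minimum fold of 1.2 and leaving out each array, plus removal of PBS 3 with leptin 4 and a clock score as covariate, the last pair chosen after seeing the data. Slides are not given in the columns used here, so batches could not be tested. The analysis used R 4.3.3, limma 3.58.1 and Python with pandas, numpy and matplotlib.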

Results

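Liver mRNA was measured in insulin-deficient mice of mixed background that received leptin or phosphate-buffered saline (PBS) into a brain ventricle (icv). Leptin is a hormone of fat tissue that acts largely through the brain. The leptin infusion delivered 25 ng in 0.11 µL per hour, and the livers of that group were taken on day 10. The volume and day are not recorded here for the PBS arrays. Each group held 6 arrays, 12 in all, numbered 1 to 6 within a group, and every mean below rests on n = 6 arrays per group unless fewer are named. The labels name each array as a sample of its own but do not tie it to a mouse, so p-values measure the spread between these samples, which may be partly technical. Between 13159 and 14431 of the 45281 probes were detected per array. Pearson correlations between arrays, taken across probes, ran from 0.940 to 0.985 within groups and from 0.921 to 0.973 between groups. No array pair was near identical, as the smallest median absolute log2 difference between any pair of arrays was 0.214. The number of arrays limits the precision.

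The comparison asked which liver transcripts differ when leptin acts in the brain of a mouse without insulin. Of 8819 genes tested, 1474 passed an adjusted p of 0.05, of which 733 were higher and 741 lower with leptin. Cyp4a14, a fatty acid omega-hydroxylase induced through PPARα, had the greatest fitted fall. Its normalized intensity was 12.69 ± 1.199 (log2, SD) with PBS and 6.22 ± 1.08 with leptin, a log2 difference of -6.48 ± 0.57 (SE, adjusted p = 2.25e-05), which is 89.0-fold. In the authors' deposited table, whose values have no background subtracted, the log2 difference was -5.21. Serpina12, which encodes the adipokine vaspin, had the greatest fitted rise, from 8.40 ± 1.24 to 12.15 ± 0.84, a log2 difference of 3.75 ± 0.53 (adjusted p = 0.000777). Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, rose from 10.02 ± 1.93 to 13.53 ± 0.40, an 11.4-fold difference (adjusted p = 0.00507).

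The 12 genes with the greatest rises also held Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1 (log2 difference 3.54 ± 0.57 SE), Serpina1e (3.16 ± 0.43), Tff3 (2.89 ± 0.55), Jaml (2.78 ± 0.45), Ces3a (2.77 ± 0.84), Dnaic1 (2.74 ± 0.34), the interferon-γ-induced chemokine Cxcl9 (2.71 ± 0.59), the clock output gene Dbp (2.65 ± 0.53) and Gvin1 (2.61 ± 0.21). Fabp5, a fatty acid-binding protein, belonged to them too, but was not detected on any of the 6 PBS arrays. Its rise was at least 5.74-fold (adjusted p = 1.3e-07), so its rank beside Serpina12 is not settled. After Cyp4a14, the falls were led by Cyp4a31 (-3.97 ± 0.43), Cyp2b10 (-3.44 ± 0.82), Cyp2b23 (-3.28 ± 0.53), Cyp2b9 (-3.18 ± 0.69), the glutathione transferases Gsta1 (-2.76 ± 0.44) and Gsta2 (-2.72 ± 0.45), Slc16a5 (-2.22 ± 0.36), the estrogen sulfotransferase Sult1e1 (-2.20 ± 0.52), the acyl-CoA thioesterase Acot3 (-2.19 ± 0.64), Bmper (-2.17 ± 0.46) and the tryptophan dioxygenase Tdo2 (-2.02 ± 0.31). With leptin, Cyp4a14, Cyp2b9 and Acot3 were detected on 5 arrays, Cyp2b23 on 4, Bmper on 3 and Sult1e1 on 2, and with PBS, Tff3 and Dnaic1 were detected on 5. The calls of Ces3a and Acot3 were each lost without any 1 of 7 arrays. Those arrays were leptin 1, 2, 3 and 6 and PBS 1, 4 and 5 for Ces3a (adjusted p 0.0661 to 0.0822), and leptin 2, 3 and 6 and PBS 1, 3, 5 and 6 for Acot3 (0.0578 to 0.0702). Both were also lost with no filter on dim probes (adjusted p = 0.102 and 0.0875) and in a two-sample comparison (0.0885 and 0.0787), and Ces3a with a variance trend (0.0555). With a clock gene score per array as a covariate, chosen after seeing the data, the calls of Ppp1r3g, Jaml, Ces3a, Dbp, Cyp2b10, Cyp2b23, Cyp2b9, Slc16a5, Sult1e1, Acot3 and Bmper were lost (adjusted p 0.0507 to 0.896). The values with the score were 0.33 for Ces3a, 0.35 for Dbp, which is itself part of the score, -0.42 for Sult1e1 and -0.57 for Bmper. The others stood at 3.06 for Ppp1r3g, 1.91 for Jaml, -2.61 for Cyp2b10, -2.47 for Cyp2b23, -2.88 for Cyp2b9, -2.14 for Slc16a5 and -2.34 for Acot3. The score nearly follows the groups, which widens standard errors, so a lost call alone does not show a smaller difference. The Cyp4a, Cyp2b, Gsta, Acot and Serpina1 families hold genes of similar sequence, so these values are uncertain as to the family member.

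**Figure D1:**
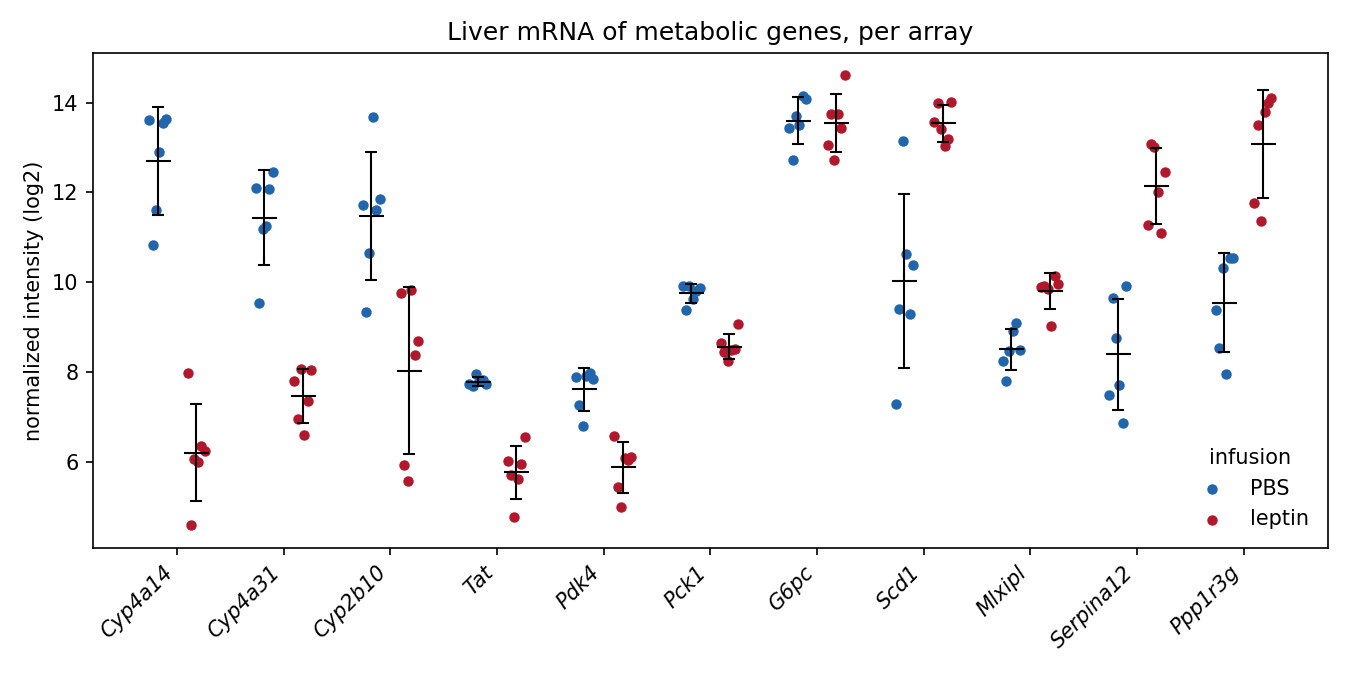
Normalized intensity (log2, y axis) of 11 metabolic genes on the 6 PBS and 6 leptin arrays, with points for arrays, horizontal dashes for means and bars for SD. Cyp4a14 lay between 10.83 and 13.64 on the PBS arrays and between 4.60 and 7.99 on the leptin arrays.

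Genes of mitochondrial and peroxisomal fatty acid oxidation were lower with leptin as a group. Of the 32 tested members of this PPARα-linked list, 17 fell, none rose and 15 did not pass, with a median log2 difference of -0.56. Besides Cyp4a14, Cyp4a31 and Acot3, the thioesterase Acot1 fell (log2 difference -2.02 ± 0.48 SE, adjusted p = 0.0131). Adjusted over the list alone, 23 members passed. The list passed camera (adjusted p = 1.2e-12), but not with an estimated correlation (adjusted p = 0.233). Pdk4, which holds pyruvate back from oxidation, fell (-1.73 ± 0.27), with detection on 5 leptin arrays. Of the 3 tested ketogenesis genes, too few for a list test, Acat1 fell (-1.38 ± 0.20, detected on 3 leptin arrays), and 2 passed when adjusted over the list alone. Fgf21, a hormone induced by PPARα, was detected on 3 PBS arrays and no leptin array, and did not pass (adjusted p = 0.0644). Its call was gained without PBS 4 (adjusted p = 0.0137). The calls of Pdk4 (-1.42, adjusted p = 0.0681) and Acot1 (-2.30, adjusted p = 0.100) were lost with the clock score, for Acot1 at a larger difference than without it.

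Urea cycle and amino acid breakdown genes were lower with leptin as well. Of 30 tested members, 17 fell, 1 rose and 12 did not pass, with a median log2 difference of -0.61. Among them Tat, the tyrosine aminotransferase, fell from 7.80 ± 0.09 to 5.78 ± 0.59 (SD), a log2 difference of -2.02 ± 0.22 (SE, adjusted p = 0.000203), with detection on 5 leptin arrays. Aass, the first enzyme of lysine breakdown (-1.88 ± 0.20), Gldc of the glycine cleavage system (-1.81 ± 0.15) and Tdo2 fell too. The member that rose was the amino acid transporter Slc38a2 (1.18), named after its value was seen. Adjusted over the list alone, 20 members passed. The list's camera adjusted p was 2.65e-10, and its adjusted p = 0.233 with an estimated correlation.

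Among gluconeogenesis genes, 4 of 13 tested members fell and none rose, with a median of -0.33. Pck1, the cytosolic PEP carboxykinase, fell from 9.76 ± 0.21 to 8.57 ± 0.27 (SD), a 2.27-fold difference (adjusted p = 0.000377), and Tat, the transcription factor Creb3l3 (-0.78 ± 0.19 SE) and the alanine aminotransferase Gpt (-0.55 ± 0.12) fell. G6pc, the catalytic subunit of glucose-6-phosphatase, stood at 13.59 ± 0.52 with PBS and 13.55 ± 0.65 with leptin (adjusted p = 0.939). Ppargc1a had a log2 difference of -0.35 ± 0.27 (adjusted p = 0.389). Adjusted over the list alone, 4 members passed, and the list passed camera (adjusted p = 0.00562) but not with an estimated correlation (adjusted p = 0.402). Of 13 genes known to be repressed by insulin through FoxO proteins, Pdk4 and Pck1 fell, also when adjusted over the list alone (2), and the list did not pass (adjusted p = 0.206). Its members Irs2 (0.49 ± 0.43), Insr (0.15 ± 0.20) and Igfbp1 (-1.14 ± 0.40, adjusted p = 0.0656) did not pass, and Igfbp1 was called without leptin 4, leptin 6 or PBS 3 (adjusted p 0.0442 to 0.0493), without PBS 3 and leptin 4 together (0.0307), with array weights (0.0368), with a replicate block (0.0183) and by the authors' p-values (0.0445).

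Fatty acid and triglyceride synthesis genes went both ways. Of 21 tested members 5 rose, 2 fell and 14 did not pass, with a median of 0.44. Besides Scd1, the carbohydrate-response factor ChREBP (Mlxipl, 1.29 ± 0.22), the elongase Elovl6 (1.12 ± 0.25) and the lipogenic transcription factor Srebf1 (1.08 ± 0.32) rose, as did Tkt (0.54), whereas the triglyceride synthesis enzymes Agpat2 (-0.76) and Dgat1 (-0.53) fell, these 3 named after their values were seen. Adjusted over the list alone, 8 members passed. The list's camera adjusted p was 0.0123, its adjusted p = 0.531 with an estimated correlation, and fry did not call it (adjusted p = 0.162). With the clock score as a covariate, the list's median turned to -0.32 (adjusted p = 0.175), and Scd1 (1.61, adjusted p = 0.344), Mlxipl (0.77, 0.182), Elovl6 (0.53, 0.423) and Srebf1 (0.08, 0.929) did not pass. The call of Srebf1 was also lost without any 1 of 8 arrays (leptin 1, 2, 3 or 6, PBS 1, 2, 4 or 5; adjusted p 0.0515 to 0.0726) and with the deposited values or no background correction (0.0518).

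In the list of glucose phosphorylation, glycolysis and glycogen synthesis, 4 of 13 tested members fell and 1 rose. The glycolytic enzymes Pgam1 (-0.74 ± 0.14), Pgk1 (-0.65 ± 0.12) and Tpi1 (-0.54 ± 0.11) fell, and the glycogen synthase Gys2 rose (0.92 ± 0.29). Adjusted over the list alone, 5 passed. The list did not pass (median -0.28, adjusted p = 0.0662), but did so without leptin 1, leptin 3, PBS 2 or PBS 4 (adjusted p = 0.0360, 0.0460, 0.0305 and 0.0463), by fry (0.0278) and with the clock score as a covariate (median -0.57, adjusted p = 0.00375). The call of Gys2 was lost without any 1 of 9 arrays (leptin 1, 2, 3, 5 or 6, PBS 2, 3, 4 or 6; adjusted p 0.0520 to 0.0900) and as a mean over its probes (0.0595). Although the list was called with the clock score, Gys2 was not (0.04, adjusted p = 0.963). Nor were Pgam1 (-0.57), Pgk1 (-0.46) and Tpi1 (-0.49), with adjusted p from 0.110 to 0.174.

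**Figure D2:**
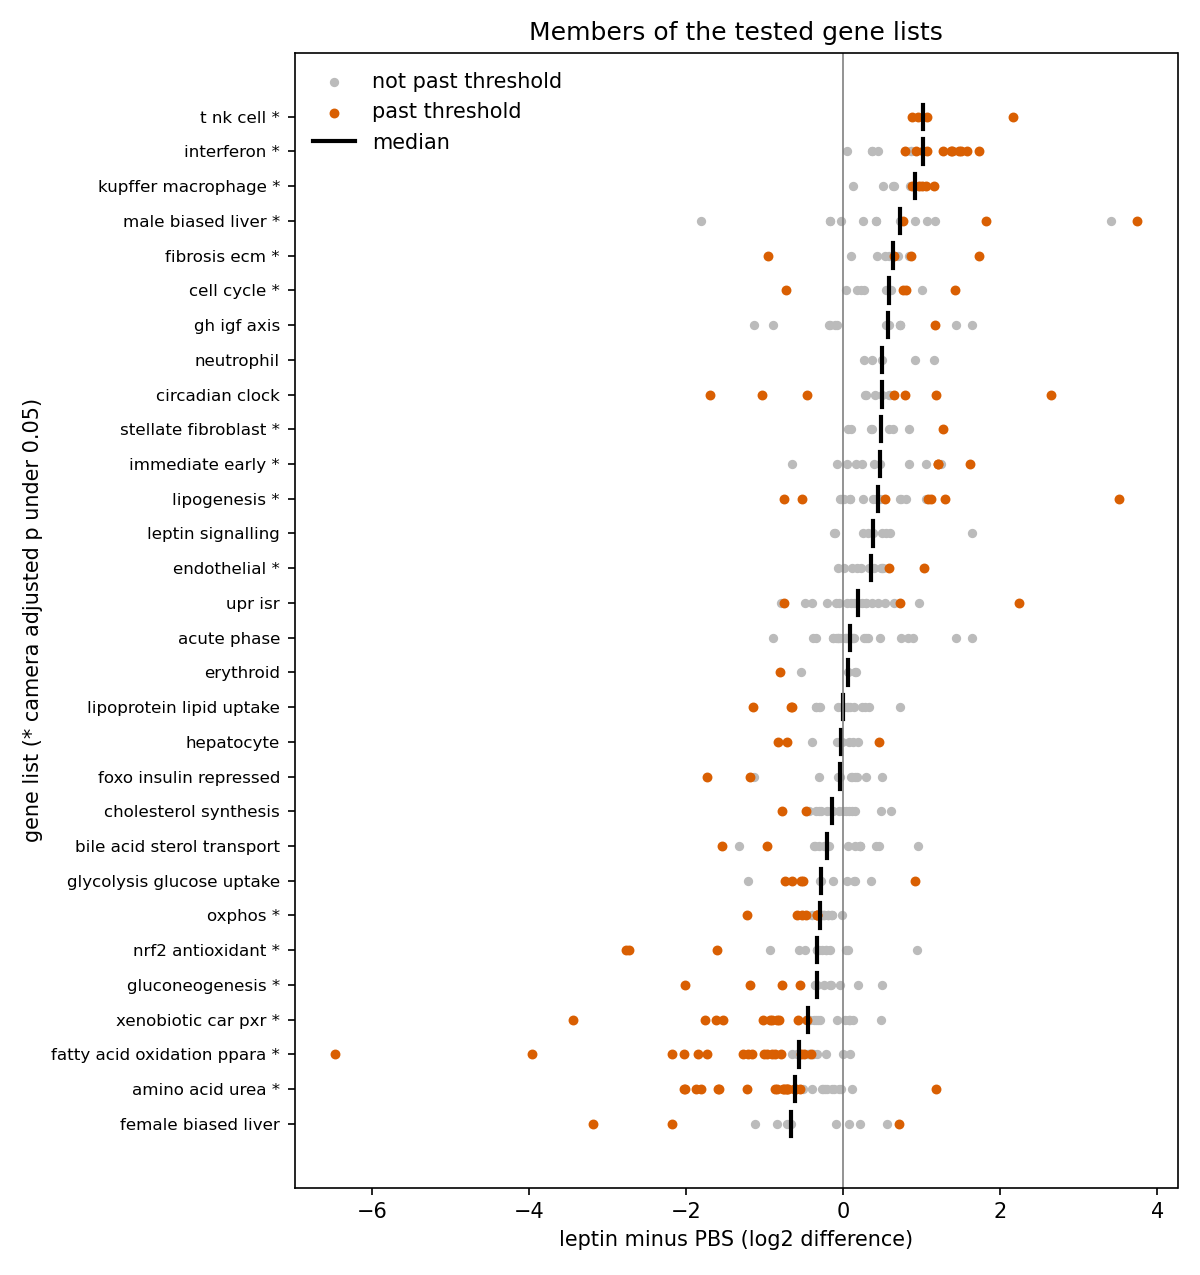
Log2 difference leptin minus PBS (x axis) of each tested member of the 30 tested gene lists (y axis), with points for genes, colour for those past the threshold and a bar at each list's median. The fitted medians ran from -0.66 for female-biased genes to 1.01 for interferon-stimulated genes and for T and NK cell markers, but with genes undetected in a group at their bounds the female-biased median was -0.27 and that of T and NK cell markers 0.61.

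Xenobiotic metabolism genes were lower with leptin. Of 24 tested members 11 fell and none rose, with a median of -0.44, and 12 passed when adjusted over the list alone. Cyp2b10, the classic target of the receptor CAR, Cyp3a25 (-1.76 ± 0.21), Gstt3 (-1.61 ± 0.21) and Cyp3a11 (-1.53 ± 0.47) fell. The camera adjusted p was 6.75e-05, and adjusted p = 0.402 with an estimated correlation. Cyp3a11 lost its call without any 1 of 7 arrays (leptin 2, 3 or 6, PBS 1, 4, 5 or 6, adjusted p 0.0624 to 0.0854). Its call was also lost without PBS 3 and leptin 4 together (0.0508), with a variance trend (0.0550) and with the clock score (-1.45, adjusted p = 0.292). Of 17 antioxidant genes, 3 fell, namely Gsta1, Gsta2 and the quinone reductase Nqo1 (-1.60 ± 0.22), and 8 passed when adjusted over the list alone. That list had a median of -0.33 and passed camera (adjusted p = 0.00162), but not with an estimated correlation (adjusted p = 0.233). Nqo1 lost its call with the clock score (-1.14, adjusted p = 0.0613). Respiratory chain genes were lower with leptin. Of 27 tested members 6 fell and none rose, with a median of -0.30, and 10 passed when adjusted over the list alone. They included Cox7b (-1.23 ± 0.28) and the ATP synthase subunits Atp5a1 (-0.59 ± 0.14) and Atp5c1 (-0.52 ± 0.13), with Ndufv1 of complex I (-0.47 ± 0.11). These 4 were not called with the clock score (adjusted p 0.0674 to 0.397), at -0.66 for Cox7b, -0.77 for Atp5a1, -0.43 for Atp5c1 and -0.54 for Ndufv1. Atp5a1, of whose 2 probes 1 was called, lost its call as a mean over them (adjusted p = 0.125). The camera adjusted p was 1.11e-05, and adjusted p = 0.402 with an estimated correlation.

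The lists of sterol and lipoprotein metabolism did not pass camera in the comparison of the groups alone. Of 18 tested cholesterol synthesis genes, Hsd17b7 (-0.78 ± 0.21) and the regulator Srebf2 (-0.48 ± 0.12) fell (list adjusted p = 0.229, 0.0206 without PBS 6, and 2 members adjusted over the list alone), and with the clock score as a covariate the list was called (median -0.58, against -0.14 without it, adjusted p = 0.000571). Of 18 bile acid and sterol transport genes, the transporters Slco1a4 (-1.55 ± 0.32) and Abcc3 (-0.97 ± 0.24) fell (list adjusted p = 0.235, and 2 adjusted over the list alone), and this list too was called with the clock score (median -0.66, against -0.20, adjusted p = 0.000117). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 difference of 0.96 ± 0.55 (adjusted p = 0.254). Of 18 lipoprotein and lipid uptake genes, 3 fell, namely Apoa4 (-1.14 ± 0.31), Apoc2 (-0.66 ± 0.21) and Apoa5 (-0.65 ± 0.16), also adjusted over the list alone (3). This list's median was above 0 at 0.0014, its mean was -0.11 and camera's direction was down (adjusted p = 0.248), while fry called it (adjusted p = 0.0204). Apoa4 lost its call without leptin 2 or PBS 1 (adjusted p 0.0505 and 0.0506), and Apoc2 without any 1 of 9 arrays (leptin 2, 3, 5 or 6, PBS 1, 2, 4, 5 or 6; adjusted p 0.0553 to 0.0864) and as a mean over its probes (0.110). Hsd17b7 lost its call without PBS 3 and leptin 4 together (adjusted p = 0.0565) and Srebf2 by the authors' p-values (0.0646). Srebf2 (-0.61), Slco1a4 (-1.79), Abcc3 (-1.20), Apoa4 (-0.35) and Apoc2 (-0.17) were not called with the clock score (adjusted p 0.0627 to 0.783).

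Of 14 tested growth hormone and IGF genes, Socs2, which is induced by growth hormone, rose (1.17 ± 0.35, adjusted p = 0.0346), and 9 members passed when adjusted over the list alone. Igf1 (-0.18 ± 0.12, adjusted p = 0.300), Ghr (0.73 ± 0.35, adjusted p = 0.176) and Igfbp2 (0.55 ± 0.22, adjusted p = 0.0978) did not pass, though another probe of Ghr (1 of 3) and of Igfbp2 (1 of 2) was called in the same direction, nor did the list (median 0.57, adjusted p = 0.213). Ghr was called without leptin 4 (adjusted p = 0.0293), without PBS 3 and leptin 4 together (0.0133) and with a replicate block (0.0323). The call of Socs2 was lost without any 1 of 7 arrays (leptin 2, 4, 5 or 6, PBS 1, 5 or 6, adjusted p 0.0532 to 0.0755). It was also lost without PBS 3 and leptin 4 together (0.0776) and with the clock score (1.43, adjusted p = 0.151). Among 9 genes of leptin receptor signalling none passed, also adjusted over the list alone (0), and 4 of the 9 had an unadjusted limma p below 0.05, as had 2836 of all 8819 genes. Socs3, a feedback inhibitor of cytokine and leptin signalling, had a log2 difference of 1.64 ± 0.58 (adjusted p = 0.0653) and Ptpn1 one of 0.60 ± 0.27 (adjusted p = 0.150). Without PBS 2 both were called (adjusted p = 0.00214 and 0.0260), as was the list (adjusted p = 0.0200 against 0.139). Without leptin 1 the list (adjusted p = 0.0360) and Socs3 (adjusted p = 0.0344) were called, and Socs3 was with array weights (0.0398) or a replicate block (0.0371).

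Among 15 genes known to be higher in male liver, 3 rose and none fell, with a median of 0.72. They were Serpina12, the peroxisomal Nudt7 (1.82 ± 0.44) and Cyp2u1 (0.76 ± 0.20, detected on 4 leptin arrays and 1 PBS array), and 6 passed when adjusted over the list alone. Camera's adjusted p was 0.0185, with adjusted p = 0.540 with an estimated correlation and 0.186 by fry. The list's call was lost without leptin 2, 3 or 6 or PBS 3 (adjusted p = 0.101, 0.0705, 0.0741 and 0.0527), with detection required on 9 arrays (0.0566) and with the clock score as a covariate (0.501). Cyp2u1 lost its call without leptin 3 or PBS 4 (adjusted p 0.0507 and 0.0513). Among 11 genes known to be higher in female liver, Cyp2b9 and Acot3 fell, Abcd2 rose by at least 1.08-fold, being undetected on all PBS arrays, and the list did not pass (median -0.66, or -0.27 with genes at their bounds, adjusted p = 0.195, and 5 adjusted over the list alone). The Y-linked Eif2s3y was detected on 6 of 6 arrays in both groups and rose by 0.45 ± 0.14, a call lost without any 1 of 9 arrays (leptin 1, 2, 3 or 6, PBS 1, 2, 3, 4 or 6; adjusted p 0.0528 to 0.0787), with a replicate block (0.0671) and by the authors' p-values (0.0757). Nudt7 (0.38), Cyp2u1 (0.78), Abcd2 (0.50) and Eif2s3y (0.23) were not called with the clock score (adjusted p 0.191 to 0.735).

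Interferon-stimulated genes were higher with leptin. Of 19 tested members 11 rose, none fell and 8 did not pass, with a median of 1.01. Oasl2 (1.73 ± 0.26, detected on 3 PBS arrays), Ifit3 (1.58 ± 0.28), the ubiquitin-like Isg15 (1.498 ± 0.28) and the immunoproteasome subunit Psmb9 (1.48 ± 0.22) rose, each with all 6 leptin arrays above the PBS mean. Adjusted over the list alone, 16 members passed. The camera adjusted p was 4.15e-09, and adjusted p = 0.296 with an estimated correlation. Markers of immune cells moved with this group. Of 12 macrophage and Kupffer cell markers 5 rose (median 0.92), among them Mpeg1 (1.16 ± 0.21), Timd4 (1.06 ± 0.32), C1qa (1.003 ± 0.25) and Clec4f (0.97 ± 0.18), and 7 passed when adjusted over the list alone (camera adjusted p = 0.000223, adjusted p = 0.402 with an estimated correlation). All 4 tested T and NK cell markers rose, also adjusted over the list alone (4). They were Ccl5 (2.16 ± 0.40, detected on 4 PBS arrays), Cd3d (1.07 ± 0.29, detected on 3 PBS arrays), and Cd3g and Cd3e, which no PBS array detected and which rose by at least 1.12-fold and 1.04-fold. Their median was 1.01, or 0.61 with those genes at their bounds (camera adjusted p = 0.000805, adjusted p = 0.296 with an estimated correlation). Timd4 lost its call without any 1 of 8 arrays (leptin 1, 3 or 5, PBS 1, 3, 4, 5 or 6; adjusted p 0.0514 to 0.0754), without PBS 3 and leptin 4 together (0.0796), with the deposited values or no background correction (0.0806), with another background method (0.0586), with a replicate block (0.0633) and by the authors' p-values (0.0543). Cd3d lost its call with the deposited values (adjusted p = 0.0530), with no background correction (0.0531), with no filter on dim probes (0.0599) and in a two-sample comparison (0.0558). Clec4f lost its call with the clock score (0.91, adjusted p = 0.0804).

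Of the B cell marker list, 2 members were tested and both rose, Cd74 by 2.31 ± 0.35 and Cd79b by 0.93 ± 0.20, the latter detected on 1 PBS array. Cd74 is counted below among the MHC class II genes, so its rise is not separate evidence of B cells. Endothelial markers had a median of 0.36, and 2 of 12 rose, Cdh5 (1.03 ± 0.23) and Stab2 (0.58 ± 0.15), with 6 adjusted over the list alone (camera adjusted p = 0.00883, adjusted p = 0.402 with an estimated correlation). Of 8 stellate cell and fibroblast markers, Acta2 rose (1.27 ± 0.29, with 1 of its 4 probes called). With the clock score Acta2 stood at 1.67 (adjusted p = 0.0507). Adjusted over this list alone, 3 passed (median 0.48, camera adjusted p = 0.0153). The list's adjusted p was 0.402 with an estimated correlation and 0.161 with the clock score. None of 5 neutrophil markers passed (0 at an unadjusted p below 0.05, median 0.50, adjusted p = 0.248), with S100a9 at 1.15 ± 0.93 and S100a8 at 0.92 ± 1.03. With the clock score the list was called (median 2.87, adjusted p = 0.00306). That value may rest on few arrays. The score departs from the grouping mainly on leptin 4 and PBS 3, where S100a8 lay at 12.44 and 6.87, and PBS 2 held 12.38. None of 3 cholangiocyte markers passed (0 unadjusted), with Sox9 at -0.82 ± 0.42 and Cldn7 at 0.20 ± 0.16 (0.81 with the clock score, adjusted p = 0.0204). Hepatocyte markers went both ways (median -0.02, adjusted p = 0.560). Of 10 tested, Ass1 (-0.72 ± 0.13) and albumin (Alb, -0.83 ± 0.25) fell and Serpina1a rose (0.46 ± 0.12), with 3 adjusted over the list alone. The Alb probe was dim, at 7.10 with PBS, where Ass1 lay between 14.24 and 14.87, so whether albumin mRNA fell is not settled. The call of Alb was lost without any 1 of 10 arrays, all but leptin 1 and PBS 2 (adjusted p 0.0554 to 0.0803), and without PBS 3 and leptin 4 together (0.0862). Tfrc alone of 5 erythroid genes passed, with a fall of -0.81 ± 0.17, and 2 passed adjusted over the list alone. The erythroid median was 0.06, the mean -0.19 and camera's direction down (adjusted p = 0.248). From small lists, the pancreatic elastase Cela2a rose (2.57 ± 0.52) and the amylase Amy2a5 fell (-0.48 ± 0.12), and the lipid droplet gene Plin4 fell (-1.50 ± 0.20, detected on 1 leptin array). Stab2, Alb, Serpina1a and Amy2a5 lost their calls with the clock score (adjusted p 0.123 to 0.282).

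**Figure D3:**
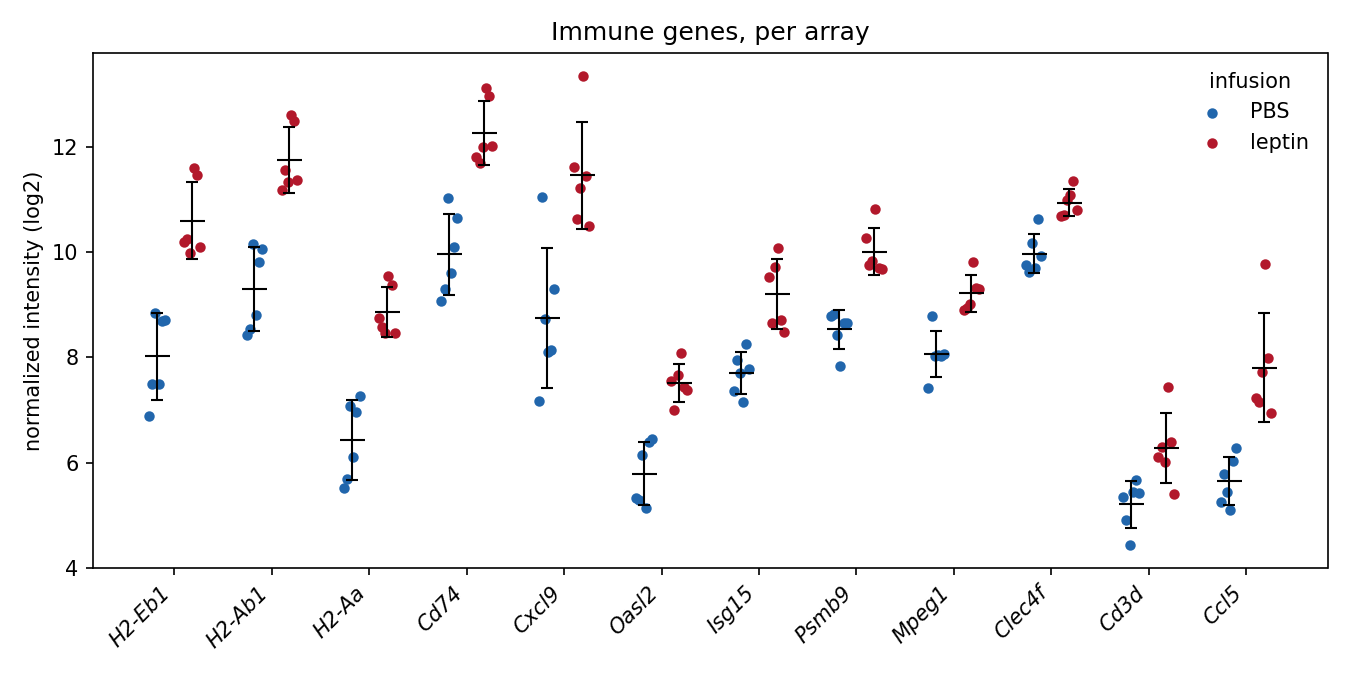
Normalized intensity (log2, y axis) of 12 immune genes on the 6 PBS and 6 leptin arrays, with points for arrays, horizontal dashes for means and bars for SD. H2-Eb1, an MHC class II gene, lay between 6.89 and 8.84 on the PBS arrays and between 9.99 and 11.61 on the leptin arrays.

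Proliferation genes were higher with leptin, with 3 of 14 tested rising and 1 falling (median 0.58, and 4 adjusted over the list alone). Cyclin D1 (Ccnd1, 1.42 ± 0.30), the replication helicase subunit Mcm4 (0.80 ± 0.24) and Cdc20 (0.76 ± 0.19, detected on 2 PBS arrays) rose, and Cdkn1a, an inhibitor of the cycle, fell (-0.73 ± 0.23). The camera adjusted p was 0.00562, adjusted p = 0.402 with an estimated correlation, 0.0566 with detection on 9 arrays and 0.0611 without PBS 3 and leptin 4 together. Mcm4 and Cdkn1a each lost their call without any 1 of 8 arrays, which were leptin 1, 3, 4 and 5 and PBS 1, 4, 5 and 6 for Mcm4 (adjusted p 0.0554 to 0.0787) and leptin 1, 2, 3 and 5 and PBS 2, 4, 5 and 6 for Cdkn1a (0.0512 to 0.0877). Mcm4 lost it also with a replicate block (adjusted p = 0.0695) and without PBS 3 and leptin 4 together (0.0581), and Cdkn1a as a mean over its probes (0.122). Ccnd1 (1.30), Mcm4 (1.15) and Cdkn1a (-0.22) were not called with the clock score (adjusted p 0.0901 to 0.751).

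Of 12 matrix and fibrosis genes, 3 rose and 1 fell (median 0.64, and 9 adjusted over the list alone). The protease inhibitor Timp1 (1.73 ± 0.27, detected on 2 PBS arrays), Sparc (0.87 ± 0.12) and Loxl1 (0.65 ± 0.21, detected on 5 PBS arrays) rose, and Ccn2 fell (-0.96 ± 0.29). The camera adjusted p was 0.00128, and adjusted p = 0.402 with an estimated correlation. Loxl1 lost its call without any 1 of 9 arrays (leptin 1, 2, 3, 5 or 6, PBS 1, 4, 5 or 6; adjusted p 0.0574 to 0.102) and Ccn2 without any 1 of 7 (leptin 1, 2, 3 or 5, PBS 2, 3 or 6; 0.0509 to 0.0776). Loxl1 was also not called with the deposited values or no background correction (adjusted p = 0.0650), with another background method (0.0567) or by the authors' p-values (0.0701). Ccn2 was not called with a replicate block (0.0664). With the clock score neither Loxl1 (0.21, adjusted p = 0.749) nor Ccn2 (-0.93, adjusted p = 0.274) was called.

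Immediate early and handling stress genes had a median of 0.46, and 3 of 13 rose, also adjusted over the list alone (3). These were Dusp1 (1.21 ± 0.28), Gadd45g (1.204 ± 0.28) and Myc, which no PBS array detected and which rose by at least 1.90-fold. The camera adjusted p was 0.0123, adjusted p = 0.402 with an estimated correlation, 0.0534 without PBS 3 and 0.155 without PBS 3 and leptin 4 together. Of 21 unfolded protein and stress response genes, the glutathione-degrading Chac1 (2.24 ± 0.65) and Pdia6 (0.73 ± 0.20) rose and the chaperone Hspa5 fell (-0.75 ± 0.19), with 4 adjusted over the list alone, and the list did not pass (median 0.18, adjusted p = 0.311). The call of Chac1 was lost without any 1 of 6 arrays (leptin 2, 5 or 6, PBS 1, 5 or 6; adjusted p 0.0554 to 0.0704) and that of Pdia6 without any 1 of 4 (leptin 3 or 5, PBS 1 or 5; 0.0504 to 0.0564). Dusp1 (1.07), Gadd45g (1.38), Chac1 (1.39), Hspa5 (-0.42) and Pdia6 (0.83) lost their calls with the clock score (adjusted p 0.0889 to 0.469). None of 24 acute phase genes passed, also adjusted over the list alone (0), 3 had an unadjusted p below 0.05, and the list's median was 0.08 (adjusted p = 0.336), with Apcs at 1.44 ± 0.58 (adjusted p = 0.104, and 0.0258 with a replicate block). Without PBS 2 the list and Apcs were called (adjusted p = 0.0434 and 0.0387), and with the clock score as a covariate the list was (median 0.50, adjusted p = 0.00956).

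Clock genes differed between the groups in both directions. Of 13 tested, 4 rose and 3 fell, also adjusted over the list alone (7). The activator Clock fell (-1.03 ± 0.14), and Arntl, its partner, fell by at least 1.95-fold, as 5 PBS arrays and no leptin array detected it, while Dbp and the repressor Bhlhe40 (1.19 ± 0.31) rose. With members of opposite phase, the list did not pass (median 0.50, adjusted p = 0.191). It was called without leptin 4 (adjusted p = 0.0382) and without PBS 3 and leptin 4 together (0.0115). With the clock score itself as a covariate it was called in the opposite direction (median -0.51, adjusted p = 0.0431), and Clock, Arntl, Dbp and Bhlhe40 were not called (0.0775 to 0.681). As the score is built from these same genes, the fit with it says nothing about them. A clock score, the mean of the standardized values of these genes signed by their relation to Dbp, lay between 0.43 and 0.95 on 5 leptin arrays and at -0.38 on leptin 4. On 5 PBS arrays it lay between -0.92 and -0.66, and on PBS 3 at 0.33. The score thus departs from the grouping mainly on leptin 4 and PBS 3, and fits with it rest largely on those arrays. On leptin 4 the immune genes Ccl5 (9.78) and Timd4 (8.15) lay above the other leptin arrays. Changes of a list's median with the score therefore cannot be assigned to clock phase. With this score as a covariate, lists called both with and without it had medians that grew over 1.5 times in gluconeogenesis (-0.69), fatty acid oxidation (-0.97), amino acid breakdown (-0.95), xenobiotic metabolism (-0.80), interferon-stimulated (1.61), proliferation (1.16) and immediate early genes (1.07) and in macrophage (1.66) and T and NK cell markers (1.82), and shrank over 1.5 times in respiratory chain (-0.19) and matrix genes (0.27).

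**Figure D4:**
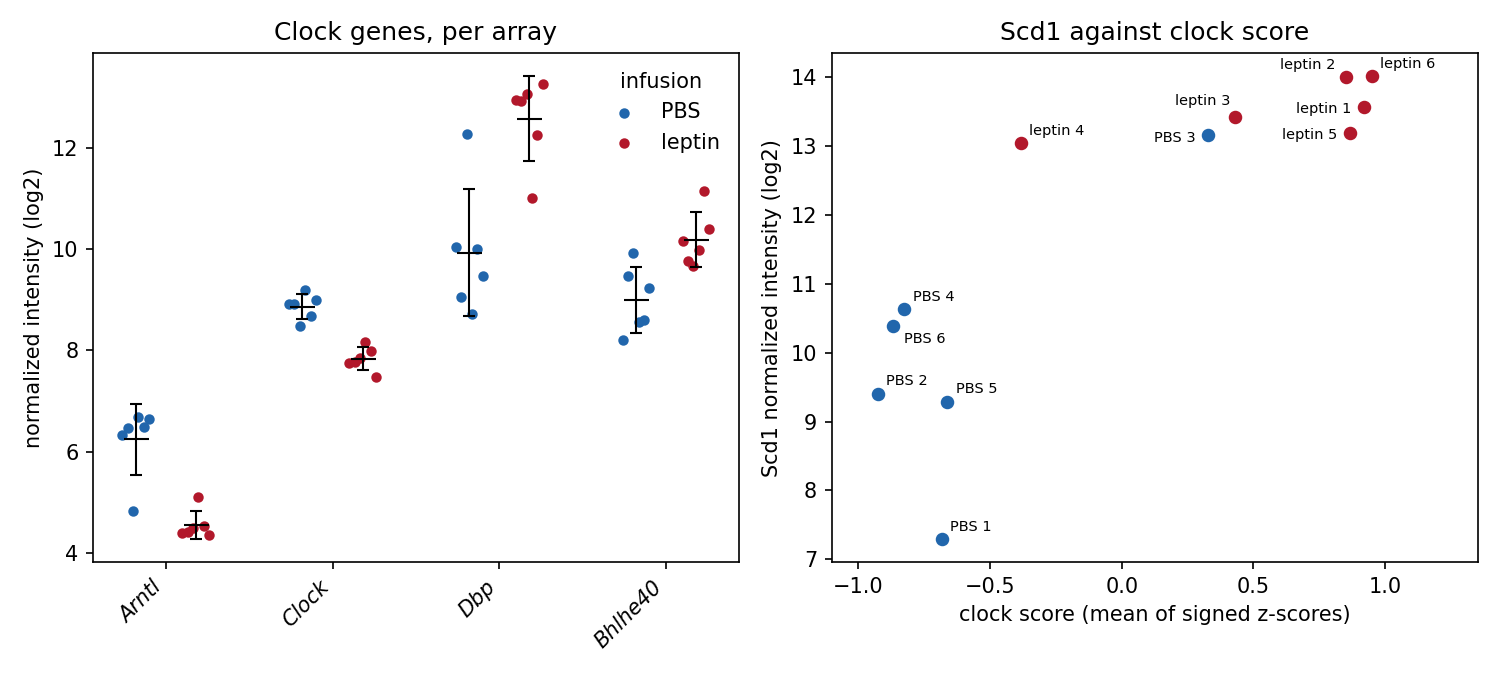
Left, normalized intensity (log2, y axis) of 4 clock genes on the 6 PBS and 6 leptin arrays, with points for arrays, horizontal dashes for means and bars for SD. Right, Scd1 (log2, y axis) against the clock score (x axis, mean of signed z-scores) on each array, where PBS 3 had an Scd1 value of 13.15 and a score of 0.33.

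In all, 16 of 30 tested lists passed camera, 10 upward and 6 downward. With an estimated correlation between genes 0 passed, with 5 at an unadjusted p below 0.05, and fry called 16, of which 14 were also called by camera. Fry tests whether a list's genes move on balance one way, and does not compare the list with other genes. In the authors' deposited table, 491 probes were marked up and 495 down at p under 0.001. Of the tested genes, 489 were represented by a marked probe, and all 489 passed here in the same direction as in the authors' deposited table. Both comparisons used the same arrays, so this is not independent support.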

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

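The tests of harvest hour, of clock phase (for the lipogenesis list and for genes outside the clock list), of the hepatocyte share, of macrophages with the clock score and of the label of PBS 3 were chosen only after the results were seen. Of 462 possible splits of the 12 arrays into 6 and 6, 100 were used, the real one included, and 1 gave as many genes as the real split, itself. The real split gave 1474 genes and the highest of the others 276, so a random grouping of the arrays seldom gives such a count. The splits not drawn were not tested. The test takes the arrays as independent, which the labels do not settle, and cannot tell the infusion from a batch that follows the groups.

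Among 236 combinations of a named gene and a group, 21 had an array far from the other 5, against 11.8 by chance at 1 in 20. Genes are not independent here, and 9 of the 21 were on leptin 4 and 5 on PBS 2. On leptin 4, Bmper (7.24), Timd4 (8.15), Ccl5 (9.78), Cd79b (6.52), Cela2a (12.47) and Arntl (5.11) lay above the other leptin arrays on the log2 scale, and Mlxipl (9.03), Creb3l3 (8.21) and Nudt7 (11.82) below them. On PBS 2, Socs3 (11.54), Ptpn1 (7.61), Timd4 (7.12) and C1qa (9.61) lay above the other PBS arrays and Alb (5.77) below. On PBS 3, Dbp (12.27) lay above and Arntl (4.84) below the other PBS arrays. On leptin 2, Cyp2b9 (4.48), Tpi1 (12.66) and Abcc3 (8.67) were low, as were Socs3 on leptin 1 (8.81) and Cyp2b9 on PBS 4 (8.26). Probes with no single gene symbol here, which the gene comparison leaves out, held 455 calls of 1994, 246 higher and 209 lower.

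The clock genes differed between the groups, 7 of 13 passing, with Arntl and Clock opposite to Dbp. Livers taken at different hours would give that, but an effect of the infusion on the clock would give the same signs, so the explanations cannot be told apart, as the hour of harvest is not given in the sources used here. For the called genes outside the clock list the prediction against clock phase as the whole cause was met. With the clock score as a covariate the median ratio of the adjusted to the unadjusted difference was 1.03 (0.887 to 1.10 with each array left out). The calls nevertheless dropped to 687, of which 451 were shared with the 1474, while the median standard error grew 1.64 times. The score nearly follows the groups, and such a covariate widens the standard error of the group difference by design. A lost call alone therefore does not show a smaller difference. What else led to the drop was not tested. For the lipogenesis list the prediction of clock phase was met, as the median went from 0.44 to -0.32 with the covariate. It lay below 0 whichever array was left out (-0.41 to -0.09, the last without leptin 4). Yet the score departs from the grouping mainly on leptin 4 (-0.38) and PBS 3 (0.33), and PBS 3 also held the highest Scd1 of the PBS arrays. This fit and the ratio above rest largely on those arrays. They cannot separate clock phase from the infusion, so the question stays open.

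The MHC class II genes H2-Aa, H2-Ab1, H2-Eb1, H2-DMa, H2-DMb1 and Cd74, chosen after their values were seen, all rose, with a median log2 difference of 2.37, or 2.31 with H2-DMb2, which rose too. The prediction against a larger share of macrophages as the only cause was met. The macrophage marker median was 0.92 (95% bootstrap interval over markers 0.64 to 1.01), below 1.19, which is 50% of the MHC class II median and was set as the bound. With the clock score it was 1.66 (1.34 to 2.52), where the class II median stayed at 2.37. That later fit rests largely on leptin 4 and PBS 3, so it cannot decide the question. A part played by a larger macrophage share stays open, as 12 of 12 macrophage markers had differences above 0. The prediction against a lower share of hepatocytes as the only cause was met, as macrophage markers exceeded endothelial markers by 0.56 (0.24 to 0.81). The medians of stellate, neutrophil and erythroid markers were 0.48, 0.50 and 0.06. That interval is over markers and does not measure the spread between livers. A part played by a lower hepatocyte share stays open, as 11 of 12 endothelial and 8 of 8 stellate markers had differences above 0. A larger share of T and NK cells met its prediction, with a marker median of 1.01 (0.88 to 2.16), or 0.61 with undetected genes at their bounds, over only 4 markers near background. That prediction asked only for an interval above 0 with members called, and set no size against the class II rise. All 4 markers had differences above 0, so resampling them could not reach 0 and the interval gives no further support. Mouse T cells carry little MHC class II, so more T cells may accompany the rise without supplying it, whereas B cells carry it and Cd79b rose (0.93), so a larger share of B cells stays open and untested, as does an effect of leptin on class II expression.

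PBS 3 resembled the leptin arrays in Scd1 (13.15, against 7.29 to 10.63 on the other PBS arrays and 13.04 to 14.01 on the leptin arrays) and in the clock genes. Over all 1537 genes called without PBS 3, 36.3% lay nearer the leptin mean. This was between the bounds set for a wrong label (above 50% or at most 33.3%), so this test alone did not decide. By the same measure PBS 2 had 38.5% of 1546 genes, and of the PBS arrays it lay nearest the leptin arrays on the first principal component (2.31). The later tests were made for PBS 3 only, so the label of PBS 2 was not examined further. For PBS 3 they argue against a leptin sample labelled PBS. Of the 15 fatty acid oxidation genes called without PBS 3, 3 (20%) lay nearer the leptin mean, a test picked once the first had left the matter undecided and after Cyp4a14 had been seen at 11.61 on PBS 3. The leptin arrays, each left out in the same way, had 70.6% to 86.6%, so PBS 3 lay 34.3 percentage points below the lowest of them, more than their range of 16.04. Without PBS 3 and leptin 4 together 1579 genes passed.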

How the results depend on the processing

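The removal of PBS 3 with leptin 4 and the clock score covariate were chosen after seeing the data. The 1474 calls (733 higher, 741 lower) and 16 list calls stayed within 1.5 times under other background and normalization methods, filters of probes, variance models, array weights and a mean over probes (1218 to 1820 genes, 13 to 17 lists). Under every alternative fitted on genes, 0 of the calls shared with the 1474 changed direction. Required to exceed a 1.2-fold change, 285 genes passed (142 higher, 143 lower), by the construction of that test. Counted as separate features, 2722 probes passed (1252 higher, 1470 lower), since more features were tested. The authors' p-values gave 998, with 468 lower, and an ordinary two-sample comparison 1254. With the clock score as a covariate 687 passed (421 higher, 266 lower), and the medians of the lipogenesis and clock lists turned to -0.32 and -0.51. That score nearly follows the groups, which widens standard errors, and it is built from the clock list. With an estimated correlation 0 lists passed camera. Leaving out 1 array gave 1053 to 1546 genes, 505 to 808 higher, 548 to 778 lower, and 14 to 19 lists. Where no construction is named, the cause was not tested. Of 118 named genes 101 were called, 83 of these whichever array was left out and 28 under every alternative, with 5 more under all but the filter of 9 arrays, which removed them, and 0 changed direction. Of the 101, 56 were lost with the clock score, 49 at the 1.2-fold minimum, 18 with no filter on dim probes (Ces3a, Acot3, Srebf1, Gys2, Apoa4, Apoc2, Socs2, Chac1, Pdia6, Cyp3a11, Mcm4, Cdkn1a, Ccn2, Loxl1, Eif2s3y, Alb, Timd4 and Cd3d), 16 in the two-sample comparison (these without Pdia6 and Eif2s3y), 6 without PBS 3 and leptin 4 together and at most 4 under any other setting with all arrays. With a replicate block 1384 genes passed. The replicate numbers did not pair the arrays, as deviations of same-numbered arrays correlated at -0.32 to 0.46, and only leptin 1 and 3 correlated best with their own number. A block by slide was not run, as slides are not given in the columns used here. Genes detected on no array of a group have bounds only.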

Other observations

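Hsd3b5, a steroid dehydrogenase of male mouse liver chosen after its values were seen, was high on leptin 2, 3 and 6 (12.21, 11.57 and 10.07 on the log2 scale) and between 4.59 and 5.26 on the other leptin arrays, and between 4.55 and 4.85 on the PBS arrays. It did not pass (adjusted p = 0.0727). The groups' values did not overlap for 642 of the 8819 genes, where a random split of the arrays would give 0.216% of genes.

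Of the called genes, 325 differed by 2-fold or more, 206 higher and 119 lower with leptin, and the median absolute log2 difference of called genes was 0.66. The first principal component held 34.9% of the variance and separated the groups, and the second held 23.0%, with leptin 4 at -39.8 and PBS 2 at -26.0 at one end.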
